A study of Rattus norvegicus with 4 samples.

How the data were processed

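The samples are 4 libraries of total RNA from cortical neurons of rat embryos of day 18, bought from a commercial supplier per the labels. Per the labels' protocols the cells were plated in a neural induction medium and kept after 24 hours in a neuronal medium with a supplement, and RNA was taken with Trizol and a column kit. The dose of topotecan and the time of exposure are not given in the sources used here. Per the labels' protocols the libraries were made with a kit for small RNA. Between 96.3% and 97.0% of each library's counts fall on protein-coding genes, so the kit as named and the table do not match in an obvious way, and the matter stays open. Groups and replicate numbers were taken from the sample titles.

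The authors deposited 1 table of whole-number gene counts for the 4 libraries, with Ensembl gene identifiers, symbols and biotypes. Per the submitters' processing notes the tools were STAR and edgeR, with no version. The genome build, the annotation, the counting tool and whether counting used the strand are not given in the sources used here. Overlapping genes, antisense genes and near-identical copies can therefore share reads. The table held 22641 rows for 21648 gene identifiers. 792 identifiers stood on several rows with identical counts, as happens when an identifier matches several symbols or Entrez numbers, and each was counted once. The number of rows without a gene name was not tallied. Some widely studied genes, Gria2 among them, have no row under their symbol and were not analysed here.

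Depth was 27347410 and 22957786 counts in DMSO and 31181382 and 25459488 in topotecan. Replicates were compared before averaging. Over genes with a summed count of at least 10, the chi-square per degree of freedom was 13.7 between the DMSO libraries and 9.77 between the topotecan libraries, so replicates differed by more than sampling noise and each was kept as 1 sample.

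The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with treatment as the only term, TMM normalisation and the low-count filter filterByExpr (minimum count 10, minimum total 15). This left 12162 genes and 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM (counts per 1e6 library counts) are given after TMM scaling, as mean ± SD over n = 2. The biological coefficient of variation was 0.0831. Where the topotecan libraries had no counts, the fold is a lower bound against 3 counts over the group. Other folds of deeply lowered genes come from summed counts, with exact 95% binomial intervals that cover counting error only.

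Gene span is the distance from start to end of the gene in a RefSeq annotation of GRCr8, used as a property of the gene without coordinates, since the authors' build is not given in the sources used here. Identifiers were matched by Entrez number (16457), symbol (1610) or synonym (269), and 3312 stayed unmatched. A span was found for 11746 of the tested genes (96.6%). Long genes were those of 100 kb or more. Span classes had limits at 10, 30, 100, 200 and 500 kb.

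Before the data were examined, 30 gene lists were fixed from textbook knowledge, 827 entries in all. They cover synaptic adhesion, glutamate receptors, GABA receptors, synthesis and transport, voltage-gated and calcium-release channels, vesicle release, postsynaptic scaffolds and kinases, autism candidates, p53 targets, topoisomerases and repair, activity-regulated genes, the unfolded protein and integrated stress response, heat shock, interferon-stimulated genes, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, the proteasome, RNA-binding and splicing regulators, miR-124 targets, the cell cycle and the cytoskeleton. The cell type lists are pan-neuronal, glutamatergic, interneuron, astrocyte, radial glia and progenitor, oligodendrocyte, microglia, endothelial, and fibroblast and mural cell markers. Lists overlap. 28 had at least 5 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists. Camera with an estimated correlation, fry and 10000 random lists matched on span and mean expression in 10 by 10 classes were alternatives. With an estimated correlation camera uses the 2 residual degrees of freedom, so it has little power with 4 libraries.

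Genes are named by a rule also fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, an average log2 CPM of at least 2, an ordinary symbol and no overlap between the groups. It added Top1, Top2b, Elavl2, Elavl3, Elavl4, Ptbp1, Ptbp2 and Rest, the 4 members with the smallest p of each list that passed camera, and up to 3 of the most abundant members of each cell type list. It also took the 5 largest rises among genes of 100 kb or more and the 5 largest falls among genes under 30 kb. Some genes that the rule took are not reported here. Cadm3, Ptprs, Hes1, Pdgfrb, Sox9, Mcm6, Pcna, Tyms, E2f1, Nefh and Pvalb were named outside the rule after their values were seen, as were the genes of the observations that say so.

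The code was tested on simulated counts drawn for the 12162 genes from the fitted means and library sizes, with 200 genes changed. It recovered 58.2% of 1.5-fold, 71.6% of 2-fold and 95.5% of 4-fold changes, with 4 false calls. With genes of 100 kb or more lowered by 0.5 on the log2 scale it called 747 of 1854 long genes lower. In that run 26 shorter genes, which had been left unchanged, were also called. With no change it called 0 long genes lower.

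Alternatives were DESeq2 1.42.0 (its size factors in edgeR, and its Wald test), library size as the only scaling, no count filter, a filter of 1 CPM in 2 libraries, limma-voom, the replicate number as a block, leaving out each library, a test against a 1.5-fold change, a threshold of 0.01, limits of 50 and 200 kb for long genes, protein-coding genes alone and genes with an average log2 CPM of at least 3. A scaling to the 25 genes under 30 kb of the pan-neuronal, vesicle release and cytoskeleton lists with at least 10 counts in every library, Tubb3 and Slc17a7 among them, was added after the data were seen. The alternative of exonic length in place of span was not run, since no exonic length was at hand.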

Results

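RNA was measured by sequencing in cultured cortical neurons of rat embryos of day 18 that had been given either the solvent DMSO or topotecan. Topotecan is an inhibitor of topoisomerase I, the enzyme that nicks and reseals 1 DNA strand to release the twist built up by transcription. The submitters gave it to lower the expression of long genes, and the series title places the experiment in a study of the neuronal microRNA miR-124 and the RNA-binding protein ELAVL3. There were 2 libraries per treatment. The DMSO libraries held 27347410 (replicate 1) and 22957786 (replicate 2) gene counts, and the topotecan libraries 31181382 and 25459488. Mitochondrial genes took 7.04% and 7.33% of the counts in DMSO and 7.85% and 6.55% in topotecan. The 10 most abundant genes took between 9.68% and 10.9%. Across genes, log2 expression correlated at r = 0.995 between the DMSO libraries and r = 0.997 between the topotecan libraries, against 0.940 to 0.943 between treatments. The labels do not say that the libraries came from separate cultures. The p-values of single genes therefore measure the spread between these samples, which may be technical. Fisher's test, camera with the preset correlation, the matched random lists and the permutations over genes take genes as their units. Their p-values rest on the spread across genes.

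The comparison of topotecan with DMSO asked which genes changed and whether long genes fell. Astrocyte and oligodendrocyte genes showed the deepest falls, neuronal genes for cell adhesion and transmitter receptors, most of them long, fell by smaller factors, and ribosomal protein genes and several markers of cortical glutamatergic neurons rose modestly. With a correlation between genes estimated from the data none of these lists passed camera. The camera adjusted p was 0.0675 for astrocyte and for oligodendrocyte genes, and 0.476 for adhesion and for glutamate receptors. It was 0.503 for GABA genes, 0.586 for ribosomal proteins and 0.611 for glutamatergic markers. That form of camera also drops to the 2 residual degrees of freedom. For oligodendrocyte markers the estimated correlation was 0.0055, below the preset 0.01, yet the unadjusted camera p went from 2.5e-44 to 0.0048. For that list the lost call does not by itself show an effect of correlation between genes. For the other lists named here the estimated correlation was above the preset value. It was 0.064 for astrocyte genes, 0.18 for adhesion and 0.13 for glutamate receptors. For GABA genes it was 0.28, for ribosomal proteins 0.34 and for glutamatergic markers 0.29. In these lists both the correlation and the degrees of freedom changed, and which of them cost the call was not separated. Aqp4 (ENSRNOG00000016043), the water channel of astrocyte endfeet, dropped from 554 ± 45.6 CPM in DMSO to 0.368 ± 0.152 CPM in topotecan (SD, n = 2 each). Lsamp, a cell adhesion gene that spans 2170 kb, dropped from 149 ± 0.234 to 24.9 ± 1.68 CPM. Neurod6, a transcription factor of cortical excitatory neurons, rose from 353 ± 19.3 to 829 ± 0.0654 CPM. Of 12162 genes tested, 2854 (23.5%) were lower in topotecan and 1970 (16.2%) were higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The falls were also the larger changes. Among the called genes 1599 fell by 2-fold or more and 566 by 8-fold or more, while 155 rose by 2-fold or more and 4 by 8-fold or more. These counts were the same with the 60 genes that had no topotecan count set at their bound. Of all calls 59.2% were lower. A scaling to 25 neuronal genes under 30 kb, chosen after the data were seen, moved the median log2 fold change of all genes from -0.01 to -0.18 and the split to 3587 lower and 662 higher genes (84.4% lower). The count of higher genes was 1208 without topotecan replicate 1 and 1260 without topotecan replicate 2.

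The 12 genes with the lowest fitted log2 fold changes, among those with an average log2 CPM of at least 2, were Sox10, Oaf, Aqp4, Timp4, Slc25a18, Gfap, Mlc1, Acsbg1, S100a16, Slc38a3, Itih3 and Enpp6. Sox10 (ENSRNOG00000011305), the transcription factor of the oligodendrocyte lineage, had 318 and 260 counts in the DMSO libraries and 0 in both topotecan libraries. This was at least 211-fold lower, taking 3 counts over the topotecan group as the floor. Oaf, also at 0 in both topotecan libraries, was at least 170-fold lower. The place of these 2 genes rests on the fit, since their bounds lie below the ratio of some genes outside the 12, such as Fabp7 (690, with an interval from 460 to 1089). Aqp4 summed to 28098 counts in DMSO and 20 in topotecan, a 1541-fold difference with an exact 95% counting interval from 998 to 2523. Gfap (ENSRNOG00000002919), the intermediate filament protein of astrocytes, summed to 2828 and 3 counts, a ratio of 1034 with an interval from 353 to 5017. Acsbg1, an acyl-CoA synthetase expressed in astrocytes, fell by 9.70 on the log2 scale (SE 0.14, edgeR adjusted p = 1.8e-14). 10 of the 12 genes span less than 30 kb, with Acsbg1 at 56.1 kb and Enpp6 at 128 kb as the exceptions. Intervals and floors cover counting error only.

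All 14 tested astrocyte markers and all 12 oligodendrocyte lineage markers fell, with median log2 fold changes of -6.56 and -6.31. The oligodendrocyte median was -5.50 with 2 members that had no topotecan count set at their bound. In the astrocyte list the glutamate transporter gene Slc1a3 dropped from 1206 ± 81.5 to 6.75 ± 0.776 CPM, and the gap junction gene Gja1 from 470 ± 36.3 to 2.43 ± 0.577 CPM. Glul, the glutamine synthetase gene, fell least in this list, with a log2 fold change of -1.99 (SE 0.07), and kept 438 ± 21.1 CPM. In the oligodendrocyte list the myelin gene Mbp had a log2 fold change of -5.44 (SE 0.17), and the progenitor receptor gene Pdgfra one of -8.71 (SE 0.21). Camera adjusted p was 8.8e-96 for astrocyte and 3.5e-43 for oligodendrocyte markers. With an estimated correlation the adjusted p was 0.0675 for both lists. Of 9 radial glia and progenitor markers 8 fell, with a median of -3.64 (camera adjusted p = 1.4e-13, adjusted p = 0.238 with an estimated correlation). The counts adjusted over the list alone were also 14, 12 and 8 for these 3 lists. Fabp7, a fatty acid binding protein gene of radial glia, was at -9.41 (SE 0.20), and Sox2, a progenitor transcription factor, at -2.40 (SE 0.14). Hes1, the remaining member, had a log2 fold change of 0.50 and did not pass.

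Cell cycle genes were lower in the same libraries. Of 27 tested members 23 fell and none rose, with a median log2 fold change of -1.81 (camera adjusted p = 8.6e-14, adjusted p = 0.276 with an estimated correlation). Cdk1, the mitotic kinase, dropped from 19.9 ± 2.04 to 0.499 ± 0.0326 CPM, and Ccnd1, the cyclin D1 gene, from 27.1 ± 6.45 to 0.174 ± 0.0774 CPM. Cdc20 and Aurkb, both needed for chromosome segregation, had log2 fold changes of -4.41 (SE 0.21) and -5.83 (SE 0.29). Mcm6, Pcna, Tyms and E2f1 did not pass. Adjusted over the list alone, 24 fell. In the fibroblast and mural cell list 3 of 5 tested genes fell and 1 rose (median -3.07, camera adjusted p = 0.165, and 0.0234 against lists matched on span and expression). The log2 fold changes were -6.37 for Pdgfrb, -3.88 for Postn, 2.24 for Lum and 0.06 for Fn1. Microglia and endothelial markers were too low to test as lists. Of 14 microglia markers with a row, 13 had fewer than 20 counts in every library, and so had 6 of 9 endothelial markers.

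**Figure D1:**
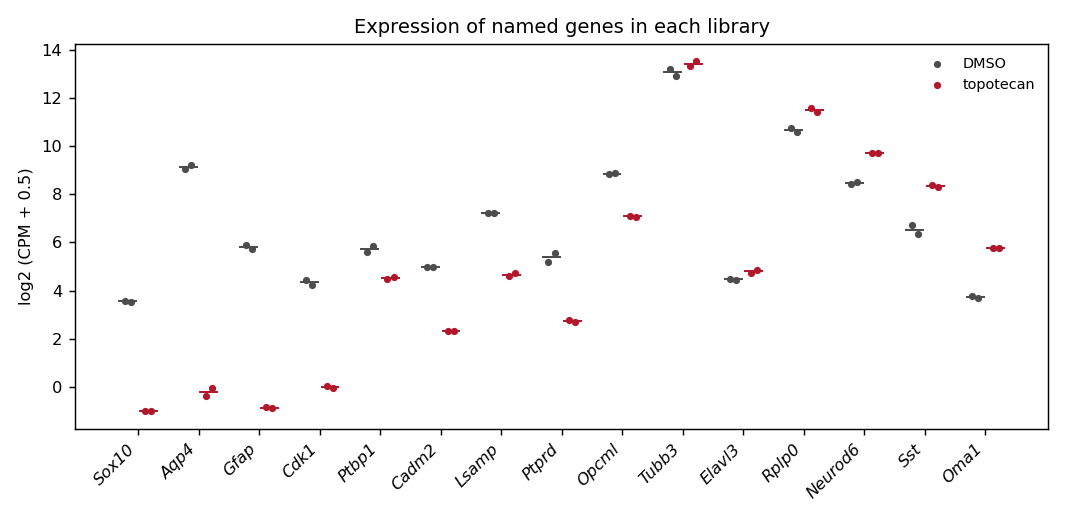
Expression of 15 named genes in each library, as log2 of TMM-normalised CPM plus 0.5 on the vertical axis. Each point is 1 library, grey for DMSO and red for topotecan, and the short line is the group mean. Sox10, Aqp4, Gfap and Cdk1 lie near the lower limit in both topotecan libraries, while Neurod6, Sst and Oma1 lie above both DMSO libraries.

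Genes that span 100 kb or more fell more often than shorter ones. Of 1898 such genes 826 (43.5%) were lower in topotecan and 115 (6.06%) higher, against 1987 (20.2%) lower and 1823 (18.5%) higher of 9848 shorter genes. The odds ratio for a fall was 3.05 (2-sided Fisher's exact test, p = 2.95e-95, treating genes as independent, which they are not). The median log2 fold change was 0.15 for 2715 genes under 10 kb, 0.06 for 3704 genes of 10 to 30 kb and -0.07 for 3429 genes of 30 to 100 kb. It was -0.19 for 1119 genes of 100 to 200 kb, -0.54 for 603 genes of 200 to 500 kb and -1.19 for 176 genes of 500 kb or more. In this last class 137 genes (77.8%) fell and 4 rose. Scaled to the 25 neuronal genes, the medians of the shortest classes turned to -0.02 and -0.10, and that of the longest was -1.36. Across 11746 genes with a known span, Spearman's rho of span with log2 fold change was -0.28 (genes are not independent replicates). Genes of 100 kb or more as a set had a camera p of 1.9e-05, and p = 0.257 with an estimated correlation. In each library, the median of long genes minus that of shorter genes, in log2 CPM relative to the mean of DMSO, was -0.06 and 0.06 in DMSO and -0.34 and -0.36 in topotecan. With 2 libraries against 2, an exact permutation test of this value cannot go below p = 0.333. The spans come from a RefSeq annotation of the assembly GRCr8, not from the authors' own, whose build is not given in the sources used here. The ribosomal protein gene Rpl29 was given 893 kb, where the median of the ribosomal list was 3.26 kb. Single spans may therefore be wrong, also in the class of 500 kb or more.

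**Figure D2:**
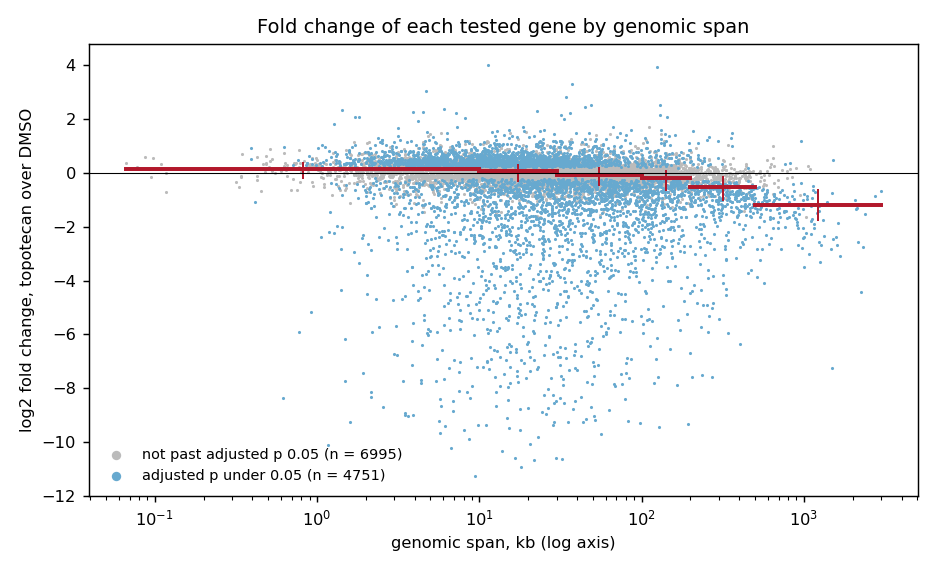
Log2 fold change of topotecan over DMSO on the vertical axis against the genomic span of each tested gene in kb on a log horizontal axis. Each point is 1 gene, blue where edgeR's adjusted p was under 0.05. Red horizontal lines are the medians of the span classes and red vertical lines their quartile ranges. The median falls from 0.15 under 10 kb to -1.19 at 500 kb or more, and most falls beyond 8-fold belong to shorter genes.

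Long genes that rose were few. The 5 largest rises among genes of 100 kb or more with an average log2 CPM of at least 2 were Oma1 (144 kb, log2 fold change 2.06, SE 0.11), Fam107b (206 kb, 1.57, SE 0.16), Stk32b (262 kb, 1.34, SE 0.14), Hs6st2 (295 kb, 1.19, SE 0.12) and Ankrd6 (140 kb, 1.18, SE 0.13). Oma1 (ENSRNOG00000007214), a protease of the inner mitochondrial membrane, went from 12.9 ± 0.541 to 53.8 ± 0.479 CPM and had the largest rise of the genes named by the rule for abundance and replicate separation. Some genes below an average log2 CPM of 2, the limit of that rule, rose by more, among them Lum by 2.24 (SE 0.33). Besides Oma1 and Fam107b, the largest rises within the limit and with separate replicates were Rgs13, Sst, Ctrb1, Lypd5, Bmp3, Gmip, Igf1, Fam221a, Ctxn2 and Igsf9, the last at 1.35 on the log2 scale. Sst, the somatostatin gene of a class of cortical interneurons, went from 93.2 ± 18.1 to 326 ± 13.1 CPM (edgeR adjusted p = 1.8e-08). Igf1, the insulin-like growth factor 1 gene, rose by 1.40 (SE 0.15).

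Genes for synaptic and axonal adhesion fell as a group. Of 47 tested members 30 fell and 2 rose, with a median log2 fold change of -0.78 (camera adjusted p = 7.7e-09, adjusted p = 0.476 with an estimated correlation). The members adjusted over the list alone included 33 that fell and 3 that rose. The falls comprised 26 of the 35 members of 100 kb or more and 4 of the 12 shorter ones. Opcml (1111 kb), which codes for a membrane-anchored adhesion protein of the same family as Lsamp, fell by 1.77 (SE 0.08, edgeR adjusted p = 4.1e-10). Lsamp fell by 2.58 (SE 0.10). Cadm2 (977 kb), a synaptic adhesion gene, had a log2 fold change of -2.78 (SE 0.14), and the receptor phosphatase gene Ptprd (2322 kb) one of -2.74 (SE 0.16). Cadm3 and Ptprs were the members that rose, by 0.64 and 0.30. Against 10000 random lists matched on span and expression, whose median was -0.30, the adhesion list lay at the 0.01 percentile (adjusted p = 0.0019). In these same topotecan libraries the astrocyte list had a median of -6.56.

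Of 21 glutamate receptor genes 12 fell and none rose (median -0.98, camera adjusted p = 4.6e-04, adjusted p = 0.476 with an estimated correlation). All 12 were among the 16 members of 100 kb or more. With p adjusted over the list alone, 14 fell. The log2 fold changes of Grm3, Gria4 and Gria3 were -1.81 (SE 0.13), -1.64 (SE 0.13) and -1.24 (SE 0.12). Of 17 genes for GABA receptors, synthesis and transport 14 fell and none rose (median -0.71, camera adjusted p = 1.2e-04, adjusted p = 0.503 with an estimated correlation). All 8 members of 100 kb or more fell, and 6 of the 9 shorter ones did too. Gabrg1, a GABA-A receptor subunit gene also expressed in glia, was at -3.65 (SE 0.15), and Gphn, the scaffold gephyrin, at -1.20 (SE 0.09). Of 31 channel genes 16 fell and none rose (median -0.63, camera adjusted p = 0.0081, adjusted p = 0.385 with an estimated correlation), with 14 of 25 long members and 2 of 6 shorter ones among the falls. Kcnip4 (1151 kb) was at -1.89 (SE 0.15) and Cacna2d1 (428 kb) at -1.25 (SE 0.12). Against lists matched on span and expression the channel genes did not stand apart (adjusted p = 0.254), whereas the glutamate receptor (0.0327) and GABA (0.0022) lists passed. The glial marker lists fell in the same libraries, as given above. Adjusted over the list alone, the counts of the GABA and channel lists stayed at 14 and 16.

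Other synaptic lists moved in both directions. Of 31 vesicle release genes 11 fell and 6 rose (median -0.04, camera adjusted p = 0.813). Of 17 postsynaptic scaffold and kinase genes 7 fell and 1 rose (median -0.24, camera adjusted p = 0.437). Of 30 cytoskeleton and transport genes 8 fell and 8 rose (median 0.03, camera adjusted p = 0.491). Of 49 autism candidate genes, many of them long, 18 fell and 2 rose (median -0.23, camera adjusted p = 0.0947), and the list passed without DMSO replicate 1 (0.0057), without a count filter (0.0316), with DESeq2 (0.0281) and with limma-voom (0.0109). Adjusted over the list alone, the falls and rises were 11 and 7 for vesicle genes, 8 and 1 for scaffolds, 8 and 8 for the cytoskeleton and 18 and 3 for autism genes. The test's direction was up for the vesicle and topoisomerase lists, against the sign of their medians. For the p53, stress response, heat shock, RNA-binding, cytoskeleton and interneuron lists the mean was below 0 and the median above.

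Genes that miR-124 is known to repress, or that mark non-neuronal cells, fell. Of 21 tested members 14 fell and none rose (median -0.95, camera adjusted p = 5.7e-06, adjusted p = 0.238 with an estimated correlation). Itgb1, an integrin subunit gene, had a log2 fold change of -2.01 (SE 0.11), Rhog, a small GTPase gene, -2.68 (SE 0.18), Vim, the vimentin gene, -3.64 (SE 0.22), and Uhrf1, a DNA methylation cofactor of dividing cells, -5.96 (SE 0.37). The list shares Vim with the progenitor markers and Sox9 with the astrocyte markers, which fell in the same libraries. Of 16 interferon-stimulated genes 12 fell and none rose (median -1.38, camera adjusted p = 4.5e-04, adjusted p = 0.385 with an estimated correlation). B2m, the light chain of MHC class I, dropped from 97.2 ± 0.207 to 19.0 ± 3.28 CPM, and Mx2 and Ddx58 had log2 fold changes of -2.96 (SE 0.21) and -6.27 (SE 0.60). Ddx58 summed to 158 counts in DMSO and 2 in topotecan. The falls adjusted over the list alone numbered 14 and 12 as before.

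Most ribosomal protein genes took a larger share of the counts in topotecan, in the same libraries where the medians of astrocyte and oligodendrocyte markers were -6.56 and -6.31. Of 62 tested members 40 rose, 22 did not pass and none fell (median 0.39, camera adjusted p = 8.9e-07, adjusted p = 0.586 with an estimated correlation). Rplp0 rose from 1647 ± 138 to 2869 ± 245 CPM, and Rpl3, Rps3 and Rpl15 by 0.49 (SE 0.07), 0.56 (SE 0.08) and 0.57 (SE 0.08) on the log2 scale. These genes have near-identical processed copies in mammalian genomes, so their counts are uncertain where the authors' counting could split reads. Of 28 proteasome genes 17 rose and none fell (median 0.25, camera adjusted p = 0.0019, adjusted p = 0.557 with an estimated correlation), among them Psmb4 by 0.49 (SE 0.08) and Psmb5 by 0.53 (SE 0.10). Matched on span and expression, the ribosomal list stood apart from random lists (adjusted p = 0.0014) and the proteasome list did not (adjusted p = 0.28). Of 62 subunits of oxidative phosphorylation 13 rose and 6 fell (median 0.12, camera adjusted p = 0.041, adjusted p = 0.75 with an estimated correlation). Ndufa8 rose by 0.44 (SE 0.08), while Ndufs1 and Cyc1 were lower, at -0.51 (SE 0.08) and -0.59 (SE 0.11). This call was lost without DMSO replicate 2 (camera adjusted p = 0.283), with library size as the only scaling (0.0609) and with a filter of 1 CPM (0.0503), and scaled to neuronal genes the list's median turned to -0.05. Under that scaling the medians of the ribosomal and proteasome lists were 0.22 and 0.08. With p adjusted over the list alone, 42 ribosomal, 20 proteasome and 12 oxidative phosphorylation genes rose.

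Of the 3 lists of neuronal markers only that of cortical glutamatergic neurons passed camera, and no test compared them with the glial lists. Of 13 markers of cortical glutamatergic neurons 7 rose and 1 fell (median 0.42, camera adjusted p = 0.0226, adjusted p = 0.611 with an estimated correlation, and 0.0535 without DMSO replicate 1). Neurod6 rose by 1.23 (SE 0.08) and Neurod1 by 0.67 (SE 0.10), both of them basic helix-loop-helix factors, and Cux1 (334 kb), an upper layer marker, fell by 0.67 (SE 0.11). Tbr1, a deep layer factor, rose by 0.73 (SE 0.20), a call lost without topotecan replicate 2 (edgeR adjusted p = 0.0651). Slc17a7, the vesicular glutamate transporter 1 gene, rose by 0.30 (SE 0.11), which passed in none of the fits without DMSO replicate 2, topotecan replicate 1 or topotecan replicate 2 (edgeR adjusted p = 0.19, 0.0578 and 0.084). Of 14 pan-neuronal markers 6 rose and 3 fell (median 0.24, camera adjusted p = 0.339), with Nefh, the heavy neurofilament gene, lower at -1.56 (SE 0.16). Tubb3, neuronal beta-tubulin, rose from 8593 ± 1298 to 10980 ± 1025 CPM, Gap43 rose by 0.26 (SE 0.07, edgeR adjusted p = 0.0844 without topotecan replicate 1) and Stmn2 was at 0.04 (SE 0.06). Scaled to neuronal genes, the calls of Tbr1, Slc17a7, Tubb3 and Gap43 were lost (edgeR adjusted p = 0.051, 0.349, 0.14 and 0.507). Slc17a7 and Tubb3 are among the 25 genes that set this scaling, so their move toward 0 is partly built in. The call of Slc17a7 was also lost with library size as the only scaling (edgeR adjusted p = 0.0574). Of 10 interneuron markers 4 rose and 3 fell (median 0.08, camera adjusted p = 0.402), with Sst higher by 1.80 and Gad1, a GABA synthesis gene, lower at -0.43 on the log2 scale, and Pvalb at 144 summed counts in DMSO and 1 in topotecan. Calb2 was at 0.10 (SE 0.17) and passed only in the fit without topotecan replicate 2 (edgeR adjusted p = 0.0123). Adjusted over the list alone, 8 glutamatergic markers rose, and the other neuronal counts did not change.

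**Figure D3:**
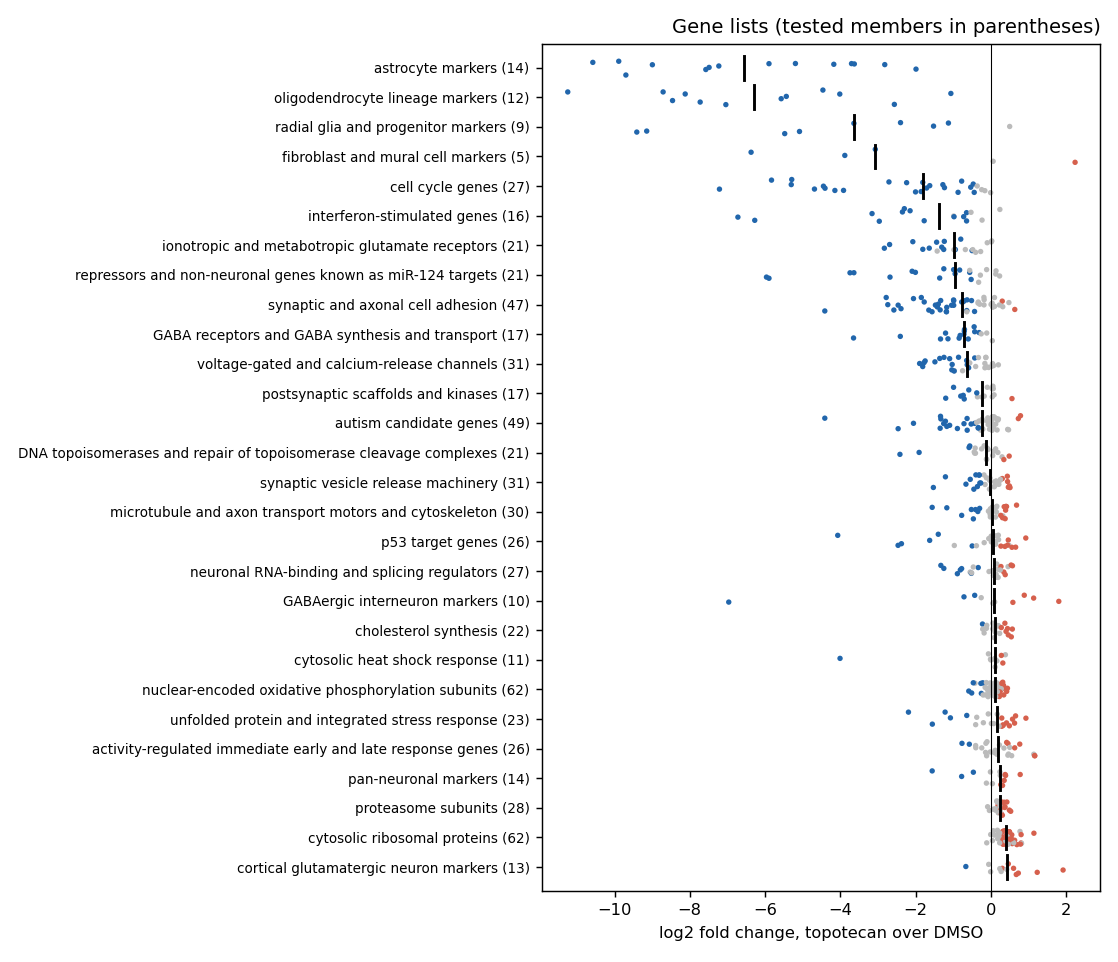
Log2 fold change of topotecan over DMSO on the horizontal axis for the tested members of 28 gene lists, with the number tested in parentheses. Points are genes, blue where lower and red where higher at an edgeR adjusted p under 0.05 and grey otherwise, spread vertically at random within a list, and black bars are medians. Astrocyte and oligodendrocyte markers lie far to the left, at medians of -6.56 and -6.31, and ribosomal proteins lie to the right of 0, at 0.39.

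The genes followed because of the drug and the study's title gave the following values. Top1, which codes for the drug's target, had 1, 2, 0 and 0 counts in the 4 libraries and was not tested. The annotation lists 2 gene numbers for its identifier, and whether Top1 reads were lost to another locus was not settled, so these counts are no measure of its level. The Top2b row, which the table annotates as a processed transcript and which held 5.10 mean CPM in DMSO, was at 0.13 (SE 0.19). Elavl3 (ENSRNOG00000013752) went from 21.6 ± 0.378 to 27.4 ± 1.37 CPM, a log2 fold change of 0.34 (SE 0.12, edgeR adjusted p = 0.0325). That call was lost with library size as the only scaling (0.0554), with the replicate number as a block (0.0583), without topotecan replicate 1 (0.0945) or 2 (0.243) and when scaled to neuronal genes (0.366). Elavl2 and Elavl4 were at 0.19 (SE 0.13) and 0.16 (SE 0.08) and passed only without DMSO replicate 2 (edgeR adjusted p = 4.2e-04 and 0.0155). Ptbp1, a splicing repressor and a known target of miR-124, dropped from 53.1 ± 6.10 to 22.3 ± 0.843 CPM (log2 fold change -1.25, SE 0.12, edgeR adjusted p = 1.4e-06). Its neuronal paralog Ptbp2 was at 0.07 (SE 0.09). Glial and progenitor markers fell in the same libraries, as given above, and these counts do not tell in which cells Ptbp1 fell. Rest, the repressor of neuronal genes, had 10 counts in each DMSO library and 5 and 2 in the topotecan libraries, too few to test.

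Stress and repair lists did not pass camera. Of 26 p53 target genes 7 rose and 6 fell (median 0.07, camera adjusted p = 0.661), and of 21 genes for topoisomerases and the repair of their DNA adducts 2 rose and 4 fell (median -0.12, camera adjusted p = 0.932). Of 23 genes of the unfolded protein and integrated stress response 10 rose and 5 fell (median 0.17, camera adjusted p = 0.619). Of 26 activity-regulated genes 6 rose and 2 fell (median 0.19, camera adjusted p = 0.0985), and this list passed fry as higher (adjusted p = 0.0182). Of 11 heat shock genes 2 rose and 1 fell (median 0.11, camera adjusted p = 0.724), and of 27 neuronal RNA-binding genes 5 rose and 7 fell (median 0.07, camera adjusted p = 0.76). Of 22 cholesterol synthesis genes 7 rose and 1 fell (median 0.11, camera adjusted p = 0.0548). The cholesterol list passed without DMSO replicate 1 (0.0403) and without topotecan replicate 1 (0.0043), without a count filter (0.046), with DESeq2 (0.0451) and with limma-voom (0.013). The RNA-binding list lay above lists matched on span and expression (adjusted p = 0.0358). Scaled to neuronal genes, the medians of the p53, heat shock, cholesterol, RNA-binding, cytoskeleton and interneuron lists turned negative. Adjusted over the list alone, the rises and falls were 7 and 7 for p53 targets, 10 and 7 for the stress response and 5 and 1 for activity-regulated genes, with the other counts as before. In all, 10 lists were lower and 4 higher of the 28 tested, and none passed camera with an estimated correlation, where 5 lists, all lower, had an unadjusted p under 0.05. Fry, which tests a list's own genes without comparing them with others, passed 12 lists lower and 4 higher.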

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

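The scaling to neuronal genes under 30 kb was chosen after the data were seen, and the other alternatives before. The replicate numbers are not shown to pair the libraries (the deviations of same-numbered libraries correlated at r = -0.0576). With the replicate block, 2746 genes were lower and 1822 higher, 803 long genes were lower, rho of span with fold change was -0.282, and 10 lists were lower and 4 higher. The count of lower genes fell to 1506 when tested against 1.5-fold and ran from 2336 to 2910 when each library was left out. The count of higher genes was 134 against 1.5-fold, 1070 at a threshold of 0.01, 662 scaled to neuronal genes, and 1208 to 2470 when each library was left out. The stricter thresholds lower the counts by construction and the scaling lowers all fold changes alike, while leaving out a library moved the counts both ways, for a cause not tested. Of the 1970 higher genes, 1138 were shared without topotecan replicate 1 and 1194 without topotecan replicate 2. A fit that leaves 1 library in a group assumes that it varies like the others. Long genes called lower numbered 1283 at 50 kb or more, 472 at 200 kb or more and 469 at an average log2 CPM of at least 3, limits that change how many genes enter, and 691 to 865 when each library was left out. The correlation of span with fold change was -0.215 without a count filter, -0.349 at an average log2 CPM of at least 3, and between -0.317 and -0.209 when each library was left out, and the cause of these shifts was not tested. With an estimated correlation 0 lists were lower and 0 higher, from 10 and 4. That form of camera uses the 2 residual degrees of freedom and has little power here. The vesicle release list, up by camera, was down by fry (median -0.036, adjusted p = 0.0239). The oxidative phosphorylation list lay below the median of matched lists, at a difference of -0.084 (adjusted p = 0.0676), though it was called up. The cause of both was not tested. Over all alternatives, named genes stayed called or uncalled in 1155 of their comparisons, lost the call in 18 and gained it in 3. Many of these genes were named for a large change or a small p in the main fit, so this tally is partly built in. No called gene changed sign, but in 10 of the 1155 an uncalled gene did. Lists stayed as they were in 383, lost the call in 22, gained it in 13 and turned direction with a call on either side in 2. Of the 383, 17 turned their test direction and 12 the sign of their median without a call on either side. Exonic length in place of span was not run. In the simulation 58.2% of 1.5-fold changes were recovered. It changed only 200 genes, against 4824 called in the data, so its adjusted threshold was the stricter one. That share is therefore no measure of how many such changes were missed in the data.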

Other observations

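The genes of this paragraph and the next were chosen after their values were seen. Ube3a (93 kb), a ubiquitin ligase gene that neurons express from the maternal copy while an antisense transcript silences the paternal one, was higher in topotecan by 0.79 on the log2 scale (SE 0.10, edgeR adjusted p = 2.9e-05). It went from 162 to 279 mean CPM and was called higher under all 12 alternative fits tried, with log2 fold changes from 0.61 to 0.96. Topotecan is known to release the paternal Ube3a copy in mouse neurons. The counts here do not separate the parental copies. Of the paternally expressed genes of the same imprinted cluster, Mkrn3 was higher by 1.20 (SE 0.15, edgeR adjusted p = 2.1e-05) and Ndn by 0.56 (SE 0.10, edgeR adjusted p = 3.9e-04). Magel2 was at 0.39 (SE 0.20, edgeR adjusted p = 0.136). Both calls held under all 12 alternatives.

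Members of the same protein families took different values. Nlgn1 (925 kb) fell by 2.06 (SE 0.14), while Nlgn2 (14.4 kb), a neuroligin of inhibitory synapses, was at -0.34 (SE 0.19) and did not pass. Nlgn3 (28.1 kb) was also lower, at -0.43 (SE 0.10, edgeR adjusted p = 0.0036), a call lost without topotecan replicate 1 (0.0709). Among the NMDA receptor subunits Grin2a (424 kb) and Grin2b (478 kb) were at -2.07 (SE 0.22) and -1.25 (SE 0.14), while the obligate subunit Grin1 (26.9 kb) was at 0.01 (SE 0.14). Of the splicing factors, Rbfox1 (2096 kb) fell by 1.33 (SE 0.08), while Rbfox2 (244 kb) rose by 0.54 (SE 0.10). Differences between family members were not tested. Among interneuron genes Pvalb summed to 144 counts in DMSO and 1 in topotecan, a ratio of 158 with a counting interval from 27.9 to 6282, while Lhx6 and Dlx1 rose by 1.14 (SE 0.23) and 0.89 (SE 0.15). Of the p53 targets Cdkn1a, the gene of the cell cycle inhibitor p21, was at -1.40 (SE 0.22) and the death receptor gene Fas at -4.07 (SE 0.53), while Aen, Trim35 and Xpc on the same list rose by 0.66 (SE 0.16), 0.56 (SE 0.09) and 0.44 (SE 0.11). Perp rose by 0.93 (SE 0.29), a call lost in 4 of the 12 alternatives, and that of Xpc was lost when scaled to neuronal genes (0.0985). The stress response genes Trib3, Ddit3 and Atf4 rose by 0.93 (SE 0.13), 0.63 (SE 0.10) and 0.49 (SE 0.10), while others on that list were lower, with Slc7a11 at -1.56 (SE 0.21), Sdf2l1 at -1.22 (SE 0.23), Dnajc3 at -1.08 (SE 0.20), Hsp90b1 at -0.64 (SE 0.08) and Phgdh, a serine synthesis gene that is abundant in astrocytes, at -2.19 (SE 0.08).

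In the weighing that follows, the tests for the fall of glial markers, and that of low counts for long genes, were chosen after the results were seen. The test over all the neuronal lists and that for ribosomal genes were chosen before. The repeat without the adhesion and receptor lists was not among the tests fixed before. Most glial and progenitor markers fell deeply, but some fell less, such as Glul at -1.99 and Sox2 at -2.40 on the log2 scale, and Hes1 did not pass. Genes lowered by 8-fold or more held 2.15% of the DMSO counts and 0.0555% of the topotecan counts. A loss of depth is argued against by the totals, where DMSO held 0.888 times the mean count of topotecan. Repression that depends on span, taken as the whole cause, is argued against by the 24 markers under 30 kb, whose median log2 fold change was -5.69 against a lower quartile of -0.25 for all genes under 30 kb. A hypothesis is that the topotecan cultures held fewer glial and dividing cells. It stays open, since the markers that prompted it cannot also test it and no cells were counted. Whether the cells died or never arose, and whether the cultures differed before treatment, was not tested.

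The fall of long genes might come from the loss of glial transcripts, if long genes were expressed more in glia. The test used 197 genes of 8 neuronal lists, leaving out those on glial, progenitor, fibroblast or cell cycle lists. Within them rho of span with fold change was -0.631 (permutation p = 1e-05, the smallest that 100000 permutations can give). The permutation treats genes as independent, which they are not. Loss of glial transcripts needed a value near 0 only if these genes are not expressed in glia, which was not checked. The median was -0.80 for the 111 of the 197 genes that span 100 kb or more, of which 77 fell. It was -0.02 for the 86 shorter ones, of which 22 fell. Without the adhesion and receptor lists, whose genes astrocytes and oligodendrocyte progenitors also express in part, rho was -0.547 over 112 genes. Low counts of long genes are argued against by rho = -0.349 at an average log2 CPM of at least 3. A share of the fall from lost glia stays open. So does a slower passage of the polymerase along long genes, which these counts do not measure.

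The rise of ribosomal protein genes might be a rescaling, in which every gene outside glia gains share once glial transcripts are gone. The ribosomal median lay 0.377 above that of 42 genes under 30 kb on the neuronal lists, where a rescaling alone needed less than 0.1. The permutation p over genes was 1e-05, the smallest that 100000 permutations can give. It treats genes as independent, which they are not. The 42 genes were not matched to the ribosomal genes on span. Lists matched on span and expression had a median of 0.19, against 0.39 for the ribosomal genes, a smaller excess. Scaled to the 25 neuronal genes, the ribosomal median also shrank, as given above. Reads shared with processed copies of these genes, and a difference between neurons and glia in ribosomal gene expression, were not tested.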
